A study of Drosophila melanogaster with 3 samples.

How the data were processed

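Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on whole pupae of Drosophila melanogaster of mixed sex. The flies carried a transgene in which green fluorescent protein (eGFP) is fused to the C-terminal end of the protein of the gene CG14655, and an antibody against GFP was used to pull down the DNA bound by the fusion protein, per the labels. The labels give an age of 48 days, which is printed here only as labelled, since it is far longer than pupal life. Chromatin was sheared by sonication with a size range of 200 to 800, per the labels. There were 3 biological replicates of 1 group, and no second condition. The deposited file listing gives the same control file for all 3 replicates, so part of any overlap between them can come from that control.

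The deposited files are peak lists in narrowPeak form, in builds dm6 and dm3. For each replicate and for the 3 replicates pooled, the authors deposited a list of candidate regions (peaks and background, meant as input for the irreproducible discovery rate procedure, IDR), each of 30000 rows. They also deposited 1 list per build of IDR-thresholded peaks, of 9981 rows in dm6 and 9405 in dm3. IDR compares the ranks of peaks between replicates to judge how many are reproducible. As the IDR list was the top of the pooled list by signal, a place in it does not show that a single peak was reproducible. The peak caller, the aligner, the IDR cutoff and the read filters are not given in the sources used here.

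The signal per peak in the deposited lists is the enrichment value of the authors' peak caller, whose scale is not stated, and it was used only to rank peaks within 1 list. The −log10 q-value in the deposited lists has a ceiling of 4.11 in the dm6 IDR list, shared by 65.2% of its peaks, and was not used for ranking. The deposited lists give the summit of each peak as an offset from its start. In 9 rows of the dm6 IDR list the offset reached or passed the width of the peak, and these rows were kept. There were 193 rows that repeated the interval of another row with a different summit, and merging overlapping peaks left 9146 regions. All 9981 dm6 IDR peaks were among the 9981 strongest pooled candidates, so the IDR list was the top of the pooled list by signal. No 2 replicate lists shared an identical interval and summit.

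No read counts are in these lists, so the depth of each replicate is unknown and no floor on detection is given. Intervals of shares are exact (Clopper-Pearson, 95%) over peaks or genes. They cover counting error only, and neighbouring peaks are not independent. Values with an SD come from the strongest 9981 candidates of each replicate (n = 3), called the top list below.

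Coordinates are dm6 unless stated, counted from 1, and were never converted between builds. The Ensembl 115 annotation and the reference sequence of the same assembly were used, and 99.9% of 16237 annotated start codons read ATG in that sequence. The annotation gave 18277 genes, 13968 of them protein-coding, with 23694 distinct transcription starts, after 5889 transposable element insertions were left out. Older symbols of 10 genes in the lists were matched to current ones.

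Recovery was the percent of IDR peaks that overlapped a peak of the top list of a replicate by at least 1 bp. Pairwise overlap was the same share between top lists, as the mean of both directions. Chance was set by 1000 circular shifts of peaks along their arms (one-sided permutation test). The promoter share was the percent of summits within 500 bp of a start, tested by 1000 shifts and by Fisher's exact test against pooled candidates that overlapped no IDR peak. Its dependence on strength was tested with Fisher's exact test (two-sided), strongest against weakest quartile by signal. Annotation classes were compared with 100 shifts. Arm counts were tested with exact binomial tests against arm length. For 50 gene lists the percent of members with an IDR summit within 500 bp of a start was compared by Fisher's exact test (two-sided), with other protein-coding genes for protein-coding lists and with all other genes for the 4 RNA gene lists. Motif and word counts within 50 bp of summits were compared with a window of the same width 300 bp away, on the left of odd-ranked and the right of even-ranked peaks, by exact McNemar tests. GC content was compared with the mean of the flanks on both sides, 300 bp away, by a sign-flip permutation test with 100000 resamples. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05.

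The gene lists, 25 motifs, tests, alternatives and naming rule were fixed before the data were examined, except where stated. The rule named the gene with the nearest start, at most 1 kb away, of each of the 20 strongest IDR peaks found in the top list of all 3 replicates. It also named the 4 members with the strongest peak of each list past the threshold, at most 2 of each other list, CG14655, and the 3 strongest peaks with no start within 1 kb.

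The alternatives were other overlap rules, other distances to starts, the stronger 50% of peaks, all candidates or the strongest 1000, protein-coding starts only, the main arms only, other backgrounds for lists and arms, other windows and word lengths, the dm3 lists, and leaving out each replicate. For dm3 the largest peak end on an arm stood for its length. In tests on IDR peaks, leaving out a replicate kept the IDR peaks that overlapped the top lists of both other replicates. These were 7836, 8037 and 7837 peaks without replicates 1, 2 and 3. The IDR list and its signal still came from all 3, so this was a stricter filter and not a new call. Added after the data were seen were rotation of bound genes along the gene order, gene sets matched on number of starts and gene length (10000 draws each), merged peaks, arm length without Y, and windows of matched GC content more than 1 kb from any pooled candidate summit. Alternatives with shifts used fewer of them.

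The procedures were tested on simulated data. In 1000 tests of the gene lists on random occupancy no list was called, and 47 of 50 lists with a large planted occupancy were recovered. There every gene had the same independent chance of being bound. The tests therefore do not cover effects of number of starts, gene length or clustering of members. No 6-mer of 2080 was called on 5000 random positions. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used. The dm3 lists were used only for counts, overlaps and arm shares, as no dm3 sequence or annotation was used here.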

Results

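The experiment mapped where the CG14655-eGFP fusion protein lies on the genome of whole Drosophila pupae. It held 3 biological replicates of a single group, so replicates were compared with each other and peaks with positions or genes of the same genome. Each replicate had 30000 candidate regions in dm6, and the IDR list held 9981 peaks. The median width of these peaks was 450 bp, and their signal ran from 134 to 7803. This median was the same in the pooled candidates, and many weak peaks across the gene Eip75B had exactly this width. It can therefore not be taken as the extent of binding. The depth of the libraries is unknown. Signal values come from the pooled list and have no replicate error, so for some peaks the rank in each replicate's own list is given.

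The strongest peak lay beside Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, in intergenic DNA at X:2703650-2704118, 27 bp from a start. It ranked 2, 1 and 1 in replicates 1, 2 and 3. The next peak, at X:12750774-12751707, lay in a non-coding exon of lncRNA:Vinr, 528 bp from a start of lncRNA:CR44619 (FBgn0265830), with ranks 1, 3 and 2. An intergenic peak at 3L:19590388-19590842 was 95 bp from a start of CG14100 (FBgn0036889) and ranked 3, 2 and 3. Among the 20 strongest peaks present in the top list of all 3 replicates, others near a start were at PNPase, a mitochondrial polynucleotide phosphorylase (FBgn0039846, signal 6083, in its 5' UTR), and the small heat shock gene Hsp27 (FBgn0001226, signal 5704). The RNA-binding protein gene larp (FBgn0261618) had a signal of 5288 in an intron. Chro (FBgn0044324), which encodes a chromatin and spindle protein, had a signal of 4747 in its 5' UTR. The remaining genes named in this way were HmgZ, CG18549, CG31145, Lk6, lncRNA:CR46035, CG13921 and CG9663, with signals of 5388, 5362, 5062, 4919, 4692, 4618 and 4527.

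The 3 strongest peaks with no start within 1 kb were all intronic. They lay in ush, which encodes a cofactor of GATA factors (2L:480558-481351, signal 6323), in CG11050 (2L:6612406-6612934, signal 6281) and in Trl, the gene of the GAGA factor (3L:14759250-14759787, signal 5687). The Trl summit was 1533 bp from the nearest start and ranked 9, 11 and 6 in replicates 1, 2 and 3.

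The replicates shared most of their strongest regions. Of the IDR peaks, 87.4% overlapped the top list of replicate 1, 86.0% that of replicate 2 and 90.2% that of replicate 3, a mean of 87.8% ± 2.14 (SD, n = 3). Shifted peaks gave means of 5.29%, 5.23% and 5.30% (permutation p = 0.001 for each, the smallest that 1000 shifts can give). The IDR list was made from the same libraries, so its recovery is not independent evidence. In all 3 top lists at once were 7316 peaks (73.3%), and in none of them 72. This share was 96.9% in the strongest quartile of IDR peaks and 21.8% in the weakest.

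Between top lists, replicates 1 and 2 overlapped by 84.0%, replicates 1 and 3 by 82.3% and replicates 2 and 3 by 79.9%, a mean of 82.1% ± 2.06 (SD, 3 pairs). Shifted lists overlapped by 5.28% to 5.31% on average (permutation p = 0.001 for each pair, the smallest possible). For the rank correlation all candidates of each replicate were used, not only the top lists. Across IDR peaks that overlapped a candidate of both replicates, the Spearman rho of signal was 0.886, 0.911 and 0.875 for these pairs. These were 9893, 9593 and 9591 peaks, and IDR peaks without a candidate in either replicate of a pair were left out. This is a relation across peaks, which are not independent replicates.

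Introns and promoters held most summits, and coding sequence held almost none. Of the IDR summits, 23.5% (2344 of 9981, exact interval 22.7% to 24.3%) lay within 500 bp of a start, against a mean of 13.5% after shifting (permutation p = 0.001, the smallest possible). Outside these promoter windows, introns held 51.3% of summits, against 39.5% of shifted ones and 50.3% of pooled candidates that overlapped no IDR peak, so this share was not specific to IDR peaks. The other candidates had 1.43% in coding sequence. Of IDR summits intergenic DNA held 22.4%, against 27.4% of shifted ones. Coding sequence outside promoter windows held 17 summits, or 0.170%, against 13% of shifted summits, and 3' UTRs 0.701% against 5.05% (permutation p = 0.0099 for each of these classes, the smallest that 100 shifts can give). The 5' UTR share outside promoter windows, 0.701% against 0.779%, did not differ by this test (one-sided permutation p = 0.208). In the replicates' top lists the coding share was 0.164% ± 0.0494 (SD, n = 3).

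**Figure D1:**
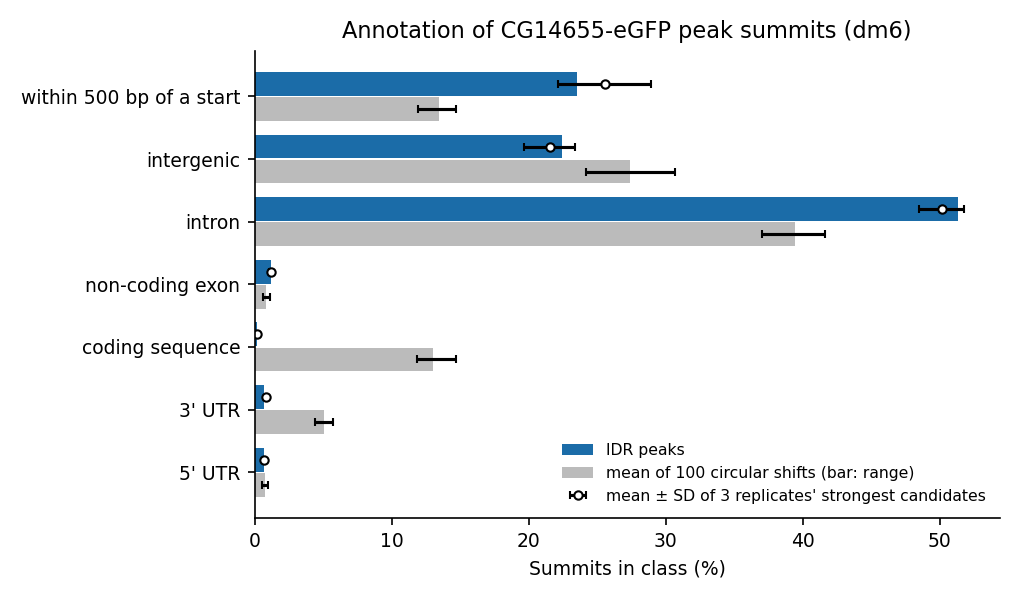
Percent of IDR summits in each annotation class (blue bars), with the mean of 100 circular shifts (grey bars, black line from lowest to highest shift) and the mean ± SD of 3 replicates' strongest candidates (open circles). Introns held 51.3% of IDR summits and coding sequence 0.170%, against 39.5% and 13% of shifted summits.

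The promoter share was 26.9%, 28.0% and 21.7% in the top lists of replicates 1, 2 and 3, a mean of 25.5% ± 3.39 (SD, n = 3). Pooled candidates outside the IDR list had 12.8% of summits near a start, an odds ratio of 2.10 (Fisher's exact p = 2.4e-114). By signal, the strongest quartile of IDR peaks had 31.4% near a start, and the other quartiles 21.5%, 19.9% and 21.2% in falling order of signal. The odds ratio between strongest and weakest was 1.70 (Fisher's exact p = 2.6e-16).

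Genes of the ecdysone response, the steroid hormone cascade that drives moulting and metamorphosis, were bound at their starts more often than other genes. Of 28 members, 15 had an IDR summit within 500 bp of a start (53.6%, exact interval 33.9% to 72.5%), against 13% of other protein-coding genes (Fisher's exact adjusted p = 6.0e-06). The members with the strongest peaks were E23, an ABC transporter (signal 3226), the cell death gene hid (signal 1873), the lactate dehydrogenase gene Ldh (signal 1822) and the nuclear receptor gene Eip75B (signal 1284). The other bound members were Eip93F, tai, EcR, ftz-f1, kay, usp, Eip74EF, ImpE3, Eip78C, ImpL2 and Eip63E, listed here after their values were seen. In the top lists of the replicates, 51.2% ± 7.43 (SD, n = 3) of the members were bound. The call did not hold against genes with a candidate region or against matched gene sets, as given with the Notch list below.

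Genes of the Notch pathway, a cell-to-cell signalling route, were also bound more often, with 8 of 16 members (50%, exact interval 24.7% to 75.3%, Fisher's exact adjusted p = 0.00288). The strongest peaks were at the corepressor gene gro (3R:26042151-26042691, signal 1929), the Notch inhibitor gene numb (2L:9449325-9449818, signal 1534), bib (2L:9984124-9984610, signal 1263) and the ubiquitin ligase gene neur (3R:9033739-9034196, signal 1175). Summits lay in introns of gro, numb and neur, and that of bib in an intron of lncRNA:CR13130. The neur peak overlapped no candidate of replicate 3. In the replicates, 47.9% ± 3.61 (SD, n = 3) of Notch members were bound. Both lists lost their calls when the background was genes with any candidate region near a start (odds ratio 1.40 and Fisher's exact adjusted p = 0.967 for ecdysone response, 2.61 and 0.906 for Notch) and when gene sets matched on starts and length were used (permutation adjusted p = 0.156 and 0.121). Matched sets had 9.66 bound members on average for ecdysone response, against 15, and 3.59 for Notch, against 8. The Notch list also lost it with starts within 200 bp (odds ratio 2.99, Fisher's exact adjusted p = 0.329).

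**Figure D2:**
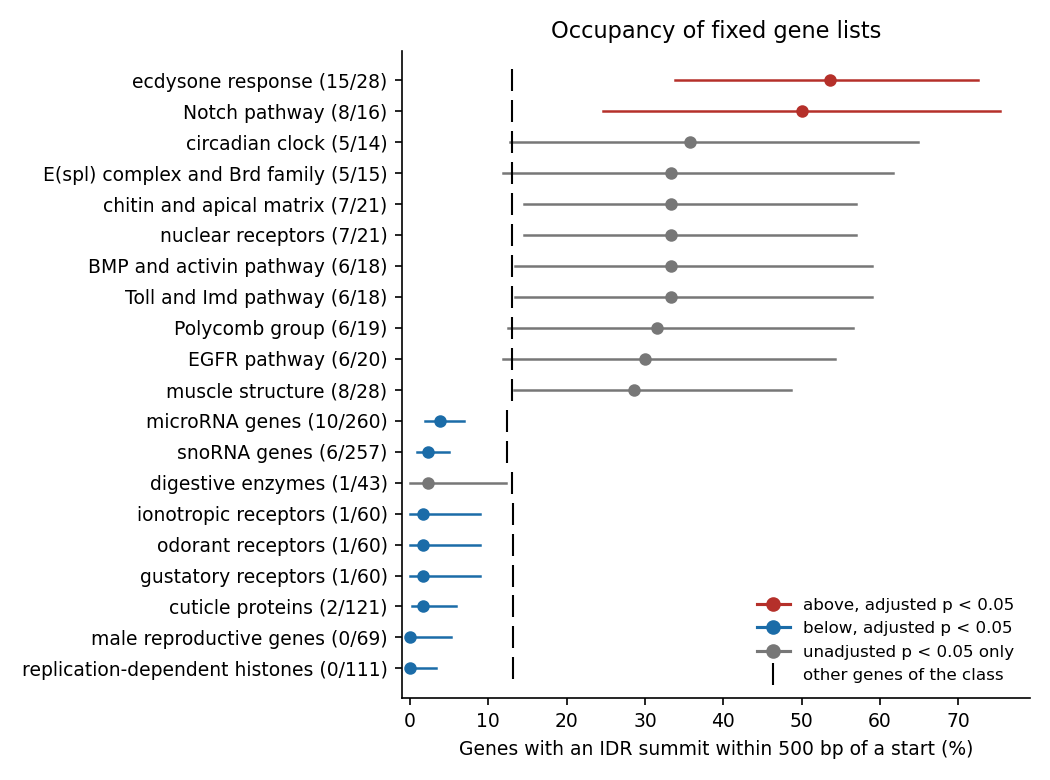
Percent of list members with an IDR summit within 500 bp of a start (points) with exact 95% intervals (lines), for lists with an unadjusted p under 0.05, and the percent of the genes each list was compared with (black ticks, other protein-coding genes, or all other genes for RNA gene lists). Ecdysone response stood at 53.6% and Notch pathway at 50%, and 8 lists lay below the other genes after adjustment.

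Eip75B (FBgn0000568, 3L:17950953-18064696, minus strand) showed how peaks lay along a long bound gene. It held 32 IDR summits, the strongest with a signal of 3225. The strongest peak within 500 bp of a start, at 3L:17999551-17999998, had its summit in the 5' UTR, 37 bp from that start, and ranked 827, 637 and 781 in replicates 1, 2 and 3. The top lists of the replicates held 29, 35 and 28 summits in the gene.

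**Figure D3:**
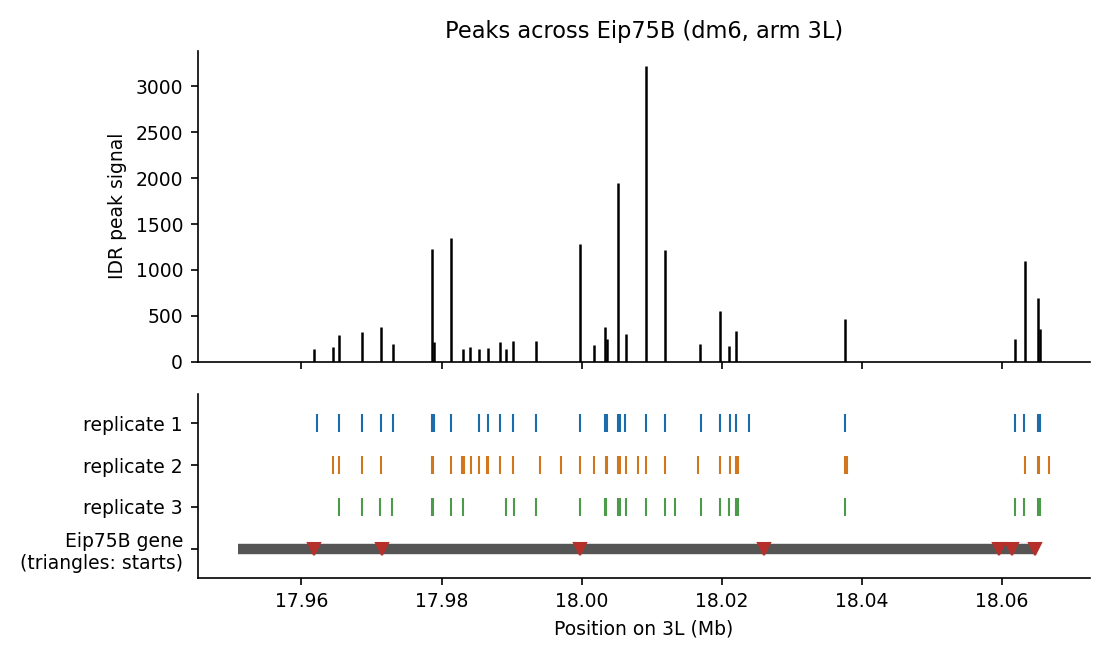
Position on arm 3L in Mb (horizontal) against the signal of IDR peaks across Eip75B (upper panel), with summits of each replicate's top list and the gene with its transcription starts (lower panel). The gene held 32 IDR summits, and 29, 35 and 28 in the top lists of replicates 1, 2 and 3.

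There were 8 lists bound less often than other genes. Chemosensory receptor genes had 1 bound member of 60 each, which were Or67a for odorant, Gr77a for gustatory and Ir67c for ionotropic receptors (1.67%, Fisher's exact adjusted p = 0.0177 each). The odds ratio was 0.112 for each. The direction held in the alternatives, but the calls did not. All 3 were lost within 200 bp (odds ratios 0.218, 0.218 and 0, Fisher's exact adjusted p = 0.355, 0.355 and 0.106 in the same order) and under rotation along the gene order (permutation adjusted p = 0.0805, 0.0811 and 0.0811). The odorant and gustatory lists also lost them without any 1 replicate (odds ratios 0.135 to 0.151, Fisher's exact adjusted p from 0.0510 to 0.109), and the ionotropic list without replicate 2 (adjusted p = 0.0942). Cuticle protein genes had 2 of 121, Cpr72Ea and Cpr50Ca (Fisher's exact adjusted p = 1.6e-04). None of 69 male reproductive genes (Fisher's exact adjusted p = 8.5e-04, but 0.0523 within 200 bp) and none of 111 replication-dependent histone genes (adjusted p = 6.0e-06) was bound. The histone call was lost with shifted peaks (permutation adjusted p = 0.0833) and under rotation (permutation adjusted p = 0.0805). Compared with all other genes, protein-coding ones included, snoRNA genes had 6 of 257 bound (Fisher's exact adjusted p = 7.0e-07) and microRNA genes 10 of 260 (adjusted p = 4.6e-05), with the strongest peaks beside snoRNA:Me28S-A774b (signal 269, no candidate in replicate 3) and mir-9377 (signal 1574). The first of these peaks was also the strongest near a start of RpS12, and the second lay in an intron of Tis11. Annotated starts of these short RNA genes (median length 134 and 92 bp) were used as listed. Whether transcription begins there was not checked, so low occupancy of either list is not a measure of binding at promoters. Against sets matched on starts and length only snoRNA genes stayed past the threshold. Against genes with a candidate region none of the 7 lists that could be tested did, although all odds ratios stayed under 1 (0.413 and Fisher's exact adjusted p = 0.429 for snoRNA genes). Histone genes could not be tested there, as they had no candidate region near a start in any dm6 list, and the near-identical copies of these genes make reads hard to place.

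The other 40 lists did not pass the threshold. Before adjustment 11 of the 50 lists lay above and 9 below at p under 0.05. Among the 40 lists that did not pass, the highest share was that of circadian clock (5 of 14). E(spl) complex and Brd family (5 of 15), nuclear receptors (7 of 21) and chitin and apical matrix (7 of 21) followed. BMP and activin pathway (6 of 18), Toll and Imd pathway (6 of 18) and Hedgehog pathway (4 of 12) had the same share as these. Adjusted p-values of all lists in this ranking ran from 0.0585 to 0.137. Of the 7 bound nuclear receptor genes, EcR, Eip75B, ftz-f1, usp and Eip78C were also bound members of the ecdysone response list. Members with strong peaks were sgg (signal 2329) and cry (signal 1553) among clock genes, Hnf4 (signal 1358) among nuclear receptors, and cact (signal 977, no candidate in replicate 3) in the Toll and Imd pathway. In the Polycomb group 6 of 19 were bound, with ph-p the strongest (signal 3695), and in the Trithorax group 6 of 22, led by brm (signal 2621). The muscle structure list had 8 of 28 bound, among them TpnC73F (signal 1789, but ranks 644, 124 and 8505 in replicates 1, 2 and 3), and the EGFR pathway 6 of 20, among them spi (signal 2829). The mitochondrial ribosomal protein list had 13 of 73 bound, with mRpS23 (signal 4392) and mRpL41 (signal 4312) among the strongest peaks.

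Relative to arm length, peaks were most frequent on 3L and sparse on arm 4, the small heterochromatin-rich chromosome. Arm 3L held 2327 peaks, 1.14 times the number its length gives (exact binomial adjusted p = 5.3e-12), and X 1892 peaks, 1.11 times (adjusted p = 2.6e-06). The excess on X was not past the threshold in the dm3 list (1.02 times, exact binomial adjusted p = 0.260). X held 19.0% of peaks in dm6 and 19.1% in dm3, where the expectation came from approximate arm lengths without Y. Arm 2R was lower, at 0.904 times (exact binomial adjusted p = 6.3e-06). Arm 4 held 15 peaks, 0.153 times (exact binomial adjusted p = 9.2e-25). Among IDR peaks found in both other top lists it stood at 0.0911, 0.0762 and 0.13 times without replicates 1, 2 and 3. Arm 3R stood at 0.970 times (exact binomial adjusted p = 0.105), but passed the threshold with annotated genes as expectation (0.955 times, adjusted p = 0.0122) and with arm length without Y (0.945 times, adjusted p = 0.00218). Arm 2L stood at 1.07 times (exact binomial adjusted p = 0.00144), but at 0.928 when annotated genes gave the expectation. No list, candidates included, had a row on Y, so its 0 peaks cannot be read as a measurement, although Y is part of the length expectation above. With the pooled candidates as expectation no arm passed the threshold. The share of arm 4 in the replicates' top lists was 0.247% ± 0.143 (SD, n = 3).

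Summits were AT-rich. Mean GC content within 50 bp of IDR summits was 33.1%, against 45.2% in the flanks, a difference of -12.2 percentage points (permutation p = 1e-05, the smallest that 100000 resamples can give). It was lower at the summit in 83.8% of peaks. Replicates' top lists gave -11.6 ± 0.996 (SD, n = 3). The dip was -15.7 in the strongest quartile and -8.84 in the weakest, and -9.31 near starts against -13.1 elsewhere. Candidates that overlapped no IDR peak had a dip of -3.65.

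**Figure D4:**
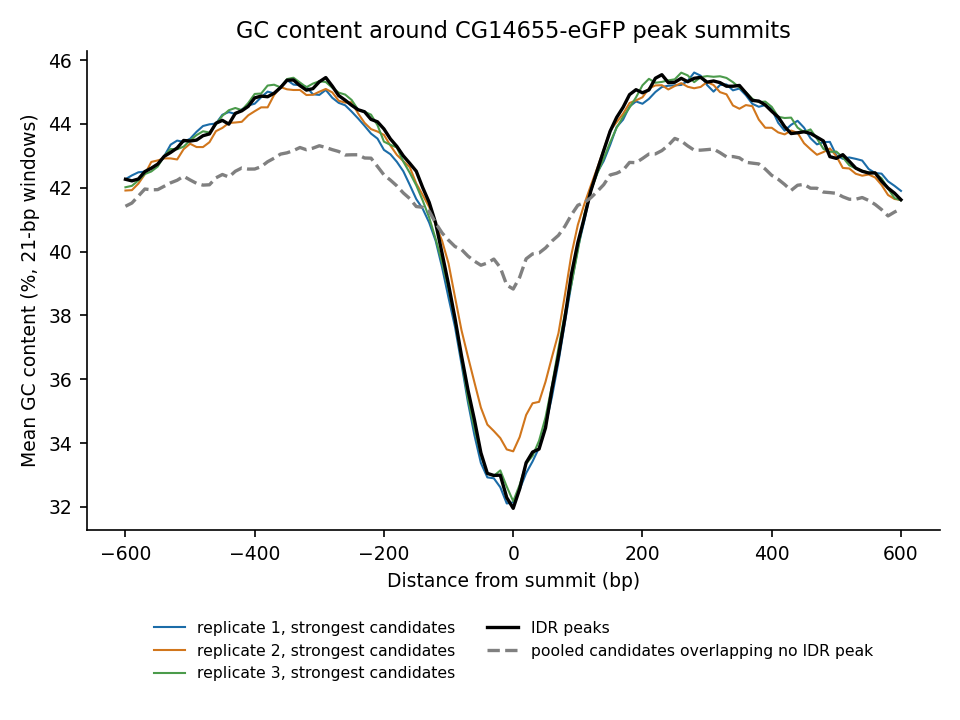
Mean GC content in percent against distance from the summit in bp, for IDR peaks (black), the top list of each replicate (coloured) and pooled candidates that overlapped no IDR peak (grey, dashed). GC content falls at the summit in every set, with summit windows averaging 33.1% GC in IDR peaks and 39.5% in the other candidates.

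Short words at summits followed this composition. Of 2080 6-mers, 609 were more frequent at summits than in flanks and 1156 less frequent. The flanks were richer in GC than DNA further from the summit, so word and motif counts against them can depend on that reference. The 6-mer TTAAAA was in 31.5% of summit windows and 11.6% of flanks (McNemar exact adjusted p = 2.5e-249), and ATATTA in 20.8% and 5.61%. Of the 25 motifs fixed in advance, 8 were higher at summits, 10 lower and 7 not different by this test. The TATA box was in 9.02% of summits and 2.95% of flanks, GATA sites in 23.1% and 14.5%, and the homeobox core TAATTA in 9.79% and 4.93%. The nuclear receptor core AGGTCA, found in ecdysone response elements, was in 1.93% and 1.77% (McNemar exact adjusted p = 0.513), and the DRE in 0.220% and 0.190% (adjusted p = 0.787).

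Against windows of matched GC content, chosen after the composition was seen, 214 6-mers were higher and 215 lower, and of the 25 motifs 3 were higher and 4 lower. The TATA box no longer differed (ratio 0.958, McNemar exact adjusted p = 0.474), TAATTA was slightly lower at summits (ratio 0.904, adjusted p = 0.0498) and GATA sites slightly higher (ratio 1.07, adjusted p = 0.0498). The GAGA motif turned from 0.556 times its flank frequency to 2.74 times that of matched windows (McNemar exact adjusted p = 1.6e-11), and the CA repeat from 0.416 to 1.38 times. GAGA was in 2.94% of summits within 500 bp of a start and 1.32% of others (Fisher's exact adjusted p = 1.5e-05). Only 12.6% of matched windows were that near a start, against 23.5% of IDR summits, and all lay more than 1 kb from any pooled candidate summit. Ratios to matched windows therefore also compare unlike kinds of region. Lower than in matched windows were also the DRE (ratio 0.5, McNemar exact adjusted p = 0.0461), the BEAF-32 core (ratio 0.888, adjusted p = 0.0224) and AGGAT, which turned from 1.3 times its flank frequency to 0.885 (adjusted p = 0.0160). The 8-mers with the smallest p over matched windows were TCAGTGCA (1.27% against 0.210%) and CAGTGCAC (1.16% against 0.190%).

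No peak was found at CG14655 itself (FBgn0037275, 3R:4777497-4780302, minus strand). Neither the IDR list, the pooled candidates nor the candidates of any replicate had a summit in the gene or within 2 kb of it. The nearest IDR summit was 8558 bp from the gene, in a peak of rank 5185.

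The builds gave similar peak counts and arm shares, and peak positions were not compared between them. The dm3 IDR list had 9405 peaks, 94.2% of the dm6 number, with 23.4% on 3L and 19.1% on X, against 23.3% and 19.0% in dm6.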

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

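In the dm3 IDR list 5 peaks lay on heterochromatic or unplaced scaffolds, 3 of them on 3LHet, 1 on XHet and 1 on Uextra. The dm6 lists had no peak outside arms 2L, 2R, 3L, 3R, 4 and X. These scaffold names occur only in the dm3 lists and coordinates were not converted. The 5 peaks may therefore have counterparts on the dm6 arms. No control samples were used here, and no cause of this difference was tested.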

How the results depend on the processing

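Of the alternatives, rotation, sets matched on starts and length, merged peaks, GC-matched windows and arm length without Y were chosen after the data were seen. Recovery of IDR peaks ranged from 71.6% (50% reciprocal overlap) to 98.5% (all candidates), and was 11.0% for the strongest 1000 of each list, a value capped by list length and not informative. The other ranges were replicate overlap from 71.7% to 86.5%, promoter share from 11.1% (200 bp) to 34.1% (1000 bp), the odds ratio by strength from 1.42 to 2.37 and the GC difference from -14.4 to -10.1, each on the same side of its test in every alternative run. The number of arms past the threshold, 5 with peaks plus Y, which had no candidate in any list, went from 6 to 0 with the pooled candidates as expectation and to 4 in dm3, where X lost its call, Y was not tested and 2L passed in the other direction. Without Y in the arm lengths it was 6, as 3R passed the threshold at 0.945. With the pooled candidates as expectation arm 2L turned to 0.960 and 2R to 1.04, and arm 2L also turned to 0.928 with annotated genes and 0.953 in dm3, where arm lengths were approximate. Arm 2L held 18.3% of peaks in dm6 and 18.2% in dm3, so the dm3 value changed mostly with the expected share. Lists above went from 2 to 4 within 1000 bp, for the stronger 50% of peaks and with the nearest start only, to 7 with shifted peaks and to 0 against genes with a candidate region. Lists below went from 8 to 5 within 200 bp (4 of the 8 and tRNA genes), 1 against genes with a candidate region (tRNA genes, odds ratio 0.305, and none of the 7 that could be tested), 4 under rotation and 1 in sets matched on starts and length. For tRNA genes the direction was not stable. Bound were 26, against 15.5 in matched sets (permutation adjusted p = 0.0700), and the odds ratio within 1000 bp was 1.07. The matched sets also gave 2 lists above, but these were mitochondrial ribosomal proteins and E(spl) complex and Brd family, not those of the main test. Leaving out each replicate gave 3 to 4 lists above and 5 to 6 below. Words higher at summits numbered 3892 as 8-mers, where more words were tested, and 214 against GC-matched windows. Apart from these, the cause was not tested. The odds ratio could not be computed for 6 lists against genes with a candidate region, as every such member was bound. No summit lay in CG14655 in the gene body alone. Over single arms, lists and genes, 938 values kept their call or strongest peak, though lists past the threshold in neither test could change side, 25 passed the threshold only in an alternative, 39 lost it, and 15 strongest peaks of genes changed. No paired analysis was possible because there was 1 group. Depth is unknown, so it cannot be said which absent peaks it limits.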

Other observations

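Matched gene sets, rotation along the gene order, arm length without Y and the GC-matched windows were tests chosen after the occupancy and the composition had been seen. Genes named in the next 3 paragraphs were chosen after their values were seen.

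Some long genes held many summits. The gene body of kirre (X:2740384-3134532), which encodes a cell adhesion protein, held 50 IDR summits, or 12.7 per 100 kb. Snoo held 36 (38.7 per 100 kb), Tet 32 (34.4), sbb 30 (37.9), fru 29 (22.1) and shn, a zinc finger gene of BMP signalling, 25 (42.9 per 100 kb). Hormone-linked genes in this group were Eip75B with 32 and Eip63E with 24. These counts carry no test of clustering.

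Annotated transposable elements held 24 IDR summits, or 0.240%, against 5.74% of shifted summits (one-sided permutation p = 0.0099, the smallest that 100 shifts can give) and 9.20% of GC-matched windows. Candidates that overlapped no IDR peak had 0.596%, so the low share was not specific to IDR peaks. How reads of repeated copies were placed is not given in the sources used here and was not tested. Neither background was limited to DNA where reads can be placed, and the GC-matched windows lay more than 1 kb from any pooled candidate summit. The low share is therefore not a measure of binding at transposable elements. Coding sequence outside promoter windows held 5.61% of the GC-matched windows, against 0.170% of IDR summits.

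Replicate 3 differed from the other replicates at some promoters and on arm 4. Its top list had a summit near 12.8% of cytoplasmic ribosomal protein genes, against 32.6% in replicate 1 and 39.5% in replicate 2. Candidate regions on arm 4 numbered 137, 182 and 38 in replicates 1, 2 and 3. No test was run on these differences, and the depth of the libraries is unknown.

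AT-rich summits were the first pattern weighed. Words chosen on odd-ranked peaks were tested on the 4990 other peaks. Of these summits 8.84% held 1 or more of 20 8-mers, against 3.47% of GC-matched windows, a ratio of 2.55 (interval 2.15 to 3.03). The ratio passed the limit set beforehand for a preferred word. Most summits held none of the words, so this does not say why summits are AT-rich. Overlapping peaks can fall in both sets, and 9.20% of matched windows lay in transposable elements, against 0.240% of IDR summits. The matched windows also lay more than 1 kb from any pooled candidate summit. Within 500 bp of a start were 12.6% of them, against 23.5% of IDR summits. A word common in candidate regions of any kind could therefore pass the limit too, so the ratio does not show a word preferred by this protein. Against flanks 300 bp away, the dip of IDR peaks was deeper than that of other candidates by 8.53 percentage points. Flank GC content was also higher in IDR peaks, 45.2% against 43.2%. An excess of AT-rich DNA in libraries or calls stays open, because the IDR list was the top of the pooled list by signal, and a bias that raises signal would deepen the dip in it too, which the bound set beforehand overlooked. No biological explanation was tested.

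The second pattern was binding at ecdysone response genes. These genes are long, with a median of 21769 bp, and gene sets matched on number of starts and length had 9.66 bound members on average, against 15 observed (p = 0.0312, two-sided permutation). The bound set beforehand was met, but the list was the highest of 50, and after adjustment over the lists the p was 0.156, so the number of starts and gene length cannot be told apart from a property of these genes. Against genes with any candidate region the odds ratio was 1.40, and open chromatin at these promoters was not analysed here.

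The third pattern was the 8 lists bound less often. Matched on starts and length, 1 of them, snoRNA genes, stayed past the threshold, 5 had an unadjusted p under 0.05, and all 8 were below the matched mean, so few starts and short genes may account for part of the pattern. Rotation left 4 past the threshold, but it changes the p and not the odds ratio, so clustering of members may account for lost calls and not for the low occupancy itself. For histone genes 0 of 111 had a candidate region near a start in any dm6 list, as unplaced reads of near-identical copies would give, and an absence of binding would give the same. No biological explanation was tested.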
